A study of Mus musculus with 3 samples.

How the data were processed

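Total RNA from mouse kidney tissue was labelled with biotin and hybridised to single-colour Affymetrix mouse expression arrays, 1 array per mouse. Per the labels, the C57BL/6 animals were given acetate, a short-chain fatty acid, in the drinking water or served as control. The 3 arrays are 1 control kidney and 2 kidneys of acetate-fed mice, named here acetate-fed mouse 1 and acetate-fed mouse 2 after their labels. Group membership was taken from the treatment agent in the labels, and no value column of the table was left unused.

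The table deposited by the authors holds 45101 probe sets on a log2 scale, with a median of 4.91 on the control array, 4.94 on acetate-fed mouse 1 and 4.93 on acetate-fed mouse 2, and nearly equal quartiles, so the values had been brought to a common distribution before deposit. MAS5 is named in the submitters' processing notes. How the log2 values were summarised, the software version and any filter are not given in the sources used here. In the deposited log2 values, 30.0% of probe sets have exactly the same value on all 3 arrays and 44.9% have exactly the same value on the 2 acetate-fed arrays. Exact ties at this rate are not a property of signals computed for each array alone, and a summary over several arrays by medians can give them; which summary was used stays unknown. No scanner file was used, so background, saturation and detection calls are unknown, and the number of arrays limits the precision of every value. With 1 control array the control has no error of its own.

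Probe sets were named through the platform annotation, updated through the Entrez identifier in a RefSeq gene table. Of 45037 probe sets that are not Affymetrix controls, 34945 had 1 gene symbol, 932 had several and were left unnamed, and 9160 were not listed in the annotation used and stayed unnamed. Of the 34945, 34741 matched the RefSeq table by Entrez identifier, and 0 symbols had to be changed. The 64 Affymetrix control probe sets were left out of every test. Tables were prepared in Python 3.11.15 with pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

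The following choices were made before the data were examined. The design foresaw linear MAS5 signals with a pseudocount, and the values as deposited should they prove to be on a log2 scale, as they did. Running the pseudocount alternatives on back-transformed values was decided after the scale was seen. The upper 60% of probe sets by mean value over the 3 arrays were tested, which kept 27022 probe sets with a mean of at least 4.21. The test was limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with an intensity trend, control against acetate, and Benjamini-Hochberg adjustment at 0.05. The fit has 1 residual degree of freedom, which comes from the acetate-fed pair, and the lone control is assumed to vary like that pair. A gene was represented by its tested probe set with the highest mean, which gave 13473 genes. A second count needed no test: probe sets at least 2-fold from the control in the same direction in both acetate-fed mice. Because both differences share the control array, this count was set beside 100 simulated sets of 3 unchanged arrays whose noise was drawn from the differences between the acetate-fed pair at like intensity.

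In all, 32 gene lists were fixed: immune and inflammatory cells and signals (T cells, T helper cytokines and regulators, B and plasma cells, macrophages and dendritic cells, neutrophils, cytokines and chemokines, antigen presentation, interferon response, complement), matrix, smooth muscle, tubular injury, nephron segments, podocytes, endothelium, urothelium, acetate and lipid metabolism, oxidative phosphorylation, acid-base and osmolyte handling, cell cycle, stress, clock and sex-dependent genes, and tissues that could have been carried over (adrenal gland, adipose tissue, red blood cells). The 31 lists with at least 5 tested genes were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Each list's median was also ranked among 10000 random lists matched on mean value in 20 bins. That percentile, and camera's p with a preset correlation, describe these 3 arrays, since genes are not replicates. Genes were named by a fixed rule: the 12 with the largest change in each direction among those past the test; up to 4 genes per list with the largest change, those with the same direction in both mice first, and all list members past the test; and Acss1, Acss2, Slc16a1, Ffar2, Ffar3, Havcr1, Lcn2, Umod, Aqp2 and the actin and Gapdh control probe sets. Some genes outside this rule are named in the closing observations, picked by hand after their values were seen from those with large changes in both mice. A few more list members are named because they went against their list or differed in direction between the mice.

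The fit was tested on simulated data, 20 runs with the 27022 means of the acetate against control comparison and 200 changed probe sets. With continuous noise it recovered 99.3% of probe sets changed 8-fold and 15.2% of those changed 2-fold, with 12.6 false calls on average. With no changed probe set it made 0.3 calls on average. When the acetate-fed pair was given the observed share of exact ties, it made 9195 calls on average with no changed probe set. The list test called a list of 20 genes shifted by 1 log2 unit in 20 of 20 runs and 1 of 400 unchanged lists; with an estimated correlation it called the shifted list in 0 of 20 runs, so that version cannot pass a list in this design. Alternatives covered the pseudocount, the filter, the normalization, the variance model, the rule for several probe sets, leaving out each acetate-fed mouse, and, added after seeing the data, leaving tied pairs out of the fit.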

Results

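Kidney expression profiles were collected from 3 C57BL/6 mice: 1 control and 2 that received 200 mM acetate in the drinking water for 6 weeks from 3 weeks of age. Acetate is the most abundant short-chain fatty acid made by gut bacteria. The comparison asks which kidney genes differ after prolonged oral acetate. All values below are deposited log2 expression values, where a difference of 1 is a 2-fold change; acetate-fed values are given as the mean ± SD of n = 2 mice, and the control as its single value. Every difference therefore includes whatever was particular to the 1 control kidney.

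Most tested macrophage (19 of 21), antigen-presentation (16 of 17), injury (15 of 19), matrix (21 of 24) and cell-cycle genes (16 of 18) were higher in both acetate-fed kidneys than in the control kidney, and all 12 adipose and 16 of 23 proximal tubule genes were lower in both. By limma's camera 15 of 31 gene lists shifted with a preset correlation, these among them, and 0 with an estimated correlation (adjusted p = 0.872 for each of these lists). The version with an estimated correlation called a truly shifted list in 0 of 20 simulated runs. Its values, repeated below, could not have come out as a call. Among 27022 tested probe sets, 93 were at least 2-fold higher and 97 at least 2-fold lower than the control in both mice, against a mean of 16.2 and 15.8 in simulated unchanged arrays that share a control. Independent lists of the same sizes would share 2.12 and 0.72 probe sets. In acetate-fed mouse 1 alone, 384 probe sets were at least 2-fold higher and 124 lower; in acetate-fed mouse 2 alone, 149 were higher and 157 lower. The control array stood at least 2-fold from both others at 190 probe sets, acetate-fed mouse 1 at 86 (81 of them above) and acetate-fed mouse 2 at 14. The differences of the 2 mice from the control had a covariance of 0.0742 across probe sets, against 0.0187 in the simulations, and a correlation of 0.81 against 0.50. The share of probe sets that differed from the control in the same direction in both mice was 54.4%, against 55.0% in the simulations. A probe set without a difference counts as not matching, and 20.5% of tested probe sets had the same value on all 3 arrays. The simulations drew noise for each array separately and did not keep such ties, so the 2 shares cannot be compared. The control could not be split to remove its part in the covariance and correlation.

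**Figure D1:**
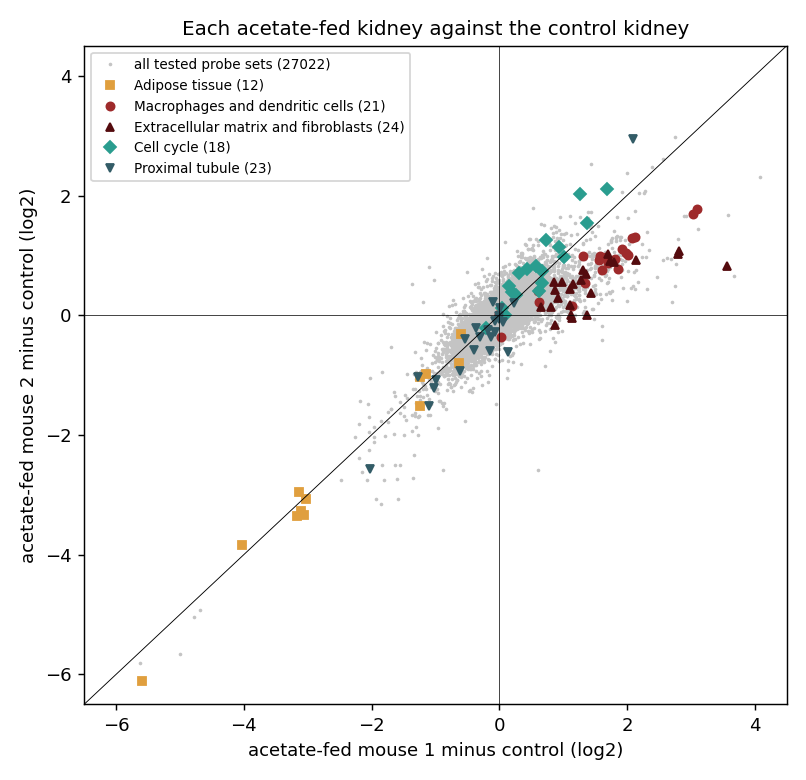
Log2 difference from the control kidney in acetate-fed mouse 1 (x axis) and acetate-fed mouse 2 (y axis) for 27022 tested probe sets (grey points), with the members of 5 gene lists in colour and the line of equal differences. Adipose genes lie at the lower left in both mice, while most macrophage and matrix genes lie to the right of the line, with larger differences in mouse 1.

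The planned limma test called 1400 probe sets higher and 1446 lower in acetate-fed kidneys. Of the 2846 calls, 92.3% were probe sets whose acetate-fed values were exactly tied, against 33.7% of all tested probe sets, and the median size of a called difference was 0.13 on the log2 scale. No probe set passed limma's test after quantile normalization or median centring, which break the ties, or in the upper 40% of probe sets (0 calls, with 4333, 4783 and 3513 at an unadjusted p under 0.05). Single-gene calls are therefore given as the planned test made them, and sizes are given per mouse; the calls named for the gene lists carry the same limit. The 12 genes with the largest increase among the calls were Cdkn1a, Ly6e, Foxo3, Map3k6, Ugt2b37, Neat1, Proser2, Junb, Krt18, Pamr1, Tra2a and Lgals3. Cdkn1a, the cell-cycle inhibitor p21, rose from 8.17 to 9.62 ± 0.03 (2.73-fold, adjusted p = 0.044). Ly6e rose 2.01-fold (adjusted p = 0.026), Foxo3, a stress-responsive transcription factor, 1.99-fold (adjusted p = 0.026), and the nuclear RNA Neat1 1.79-fold (adjusted p = 0.025). Lgals3, galectin-3, rose 1.65-fold (adjusted p = 0.026). Another tested probe set of Neat1 differed by 0.036 and another of Proser2 by 0 on the log2 scale. The 12 with the largest decrease were Adig, Cyb561a3, F5, Prkar2b, Smlr1, Rdh16, 3110045C21Rik, Lrtm2, Grip1, Pdk4, Cyp7b1 and Slc25a10. Adig, an adipocyte gene, fell 8.28-fold (adjusted p = 0.021), Cyb561a3 2.40-fold (adjusted p = 0.014), F5, coagulation factor V, 2.25-fold (adjusted p = 0.019), and Slc25a10, the mitochondrial dicarboxylate carrier, 1.83-fold (adjusted p = 0.019).

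Macrophage and dendritic cell genes were higher in both acetate-fed kidneys at 19 of 21 tested genes, 7 of them at least 2-fold in both mice, with a median difference of 1.67 in mouse 1 and 0.93 in mouse 2. Lyz2, macrophage lysozyme, was 8.49 in the control and 10.93 ± 0.93 in the acetate-fed kidneys, 8.58-fold higher in mouse 1 and 3.43-fold in mouse 2. Its near-identical paralog Lyz1, whose probes may pick up the same transcript, was 8.23-fold and 3.22-fold higher. Ms4a7 was 4.36-fold and 2.48-fold higher, and the lysosomal protease cathepsin S gene Ctss 4.22-fold and 2.46-fold. None of the 21 passed the planned test (0 over all genes and 0 adjusted over the list alone). With exactly tied pairs left out of the fit, an alternative chosen after seeing the data, 17 of the 21 passed limma's test as higher. That fit took its spread mostly from all probe sets together, with 26.5 degrees of freedom against 1 from the acetate-fed pair. A pass without the tied pairs, here and in the lists below, therefore reflects the size of the mean change more than agreement between the mice. The list shifted upwards by camera (adjusted p = 0.0026; adjusted p = 0.872 with an estimated correlation).

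Antigen-presentation genes were higher in both mice at 16 of 17 tested genes, 5 of them at least 2-fold (camera adjusted p = 0.0015; adjusted p = 0.872 with an estimated correlation). The MHC class II genes led: H2-Eb1 was 3.54-fold and 2.49-fold higher, H2-Aa 3.54-fold and 2.45-fold, the invariant chain Cd74 3.38-fold and 2.36-fold, and H2-Ab1 3.36-fold and 2.33-fold. No member passed the planned test by either adjustment (over all genes, or adjusted over the list alone), and 11 passed as higher without the tied pairs. Among 20 cytokine and chemokine genes, 16 were higher in both mice and 1 lower, with none past the planned test by either adjustment (camera adjusted p = 0.044; adjusted p = 0.872 with an estimated correlation). The camera call was also lost in the upper 40% of probe sets (adjusted p = 0.091), and without the tied pairs 6 members passed as higher and 1 as lower. The monocyte chemoattractant Ccl12 was 5.09-fold and 2.13-fold higher, Ccl8 3.05-fold and 1.76-fold, and the interferon-induced Cxcl9 3.01-fold and 1.20-fold. Ccl28, an epithelial chemokine, went the other way, 4.19-fold and 6.74-fold lower. Of 20 interferon-response genes, 14 were higher in both mice and 2 lower (camera adjusted p = 0.0032; adjusted p = 0.872 with an estimated correlation). Irf7 (1.48-fold), Ifit2 (1.24-fold) and Oas2 (1.11-fold) rose in the planned test, 3 genes over all genes and 3 adjusted over the list alone. Oasl2 was 2.23-fold and 1.75-fold higher, while Gbp3 was 1.58-fold and 2.10-fold lower.

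Of 8 T cell genes, 2 were higher in both mice, and the median difference was 0.07 in mouse 1 and 0.00 in mouse 2 (camera adjusted p = 0.27, and 0.033 with no filter). Cd3d, a T cell receptor subunit, was 1.61-fold and 1.17-fold higher. Cd8a, the CD8 co-receptor, rose 1.05-fold in the planned test, the 1 T cell call by either adjustment, while another tested Cd8a probe set was lower (log2 difference -0.056). Of 5 tested T helper cytokine and regulator genes, 3 were higher in both mice (camera adjusted p = 0.039; adjusted p = 0.872 with an estimated correlation, and 0.071 with no filter). Ccr6, a chemokine receptor of T helper and B cells, rose 1.25-fold, the 1 call of that list by either adjustment. Among 8 B and plasma cell genes, Ighm, the immunoglobulin M heavy chain, was 2.42-fold and 2.00-fold higher. Jchain was 1.98-fold higher in mouse 1 and 1.20-fold lower in mouse 2, and Mzb1 rose 1.12-fold, the 1 call by either adjustment (list camera adjusted p = 0.21). The neutrophil genes S100a8 and S100a9, which encode calprotectin, were 6.49-fold and 4.90-fold higher in mouse 1 and 1.91-fold and 1.96-fold higher in mouse 2, but the list of 8 did not pass (camera adjusted p = 0.14), and Ltf, at 1.06-fold, was its 1 call by either adjustment. Of 8 complement genes, 5 were higher and 2 lower in both mice (camera adjusted p = 0.89), although the list median of 0.43 lay at percentile 99.99 of matched random lists. Serping1, the C1 inhibitor, was 2.58-fold and 1.69-fold higher, and Cd55, a complement regulator, fell 1.39-fold, the 1 call by either adjustment. The acetate-fed values of Cd55 were exactly tied, and the complement genes that passed without the tied pairs were all higher.

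Tubular injury genes were higher in both mice at 15 of 19 tested genes and lower at 3, with medians of 0.86 in mouse 1 and 0.45 in mouse 2 (camera adjusted p = 0.0069; adjusted p = 0.872 with an estimated correlation). Lcn2, the tubular injury marker NGAL, was 6.36 in the control and 9.56 ± 1.25 in the acetate-fed kidneys, 16.9-fold higher in mouse 1 and 4.95-fold in mouse 2. Havcr1, the proximal tubule injury marker KIM-1, was 12.8-fold higher in mouse 1 and 1.58-fold in mouse 2, and the adhesion receptor Cd44 6.82-fold and 1.81-fold. Another tested Havcr1 probe set was 4.01 in the control, 6.71 in mouse 1 and 4.22 in mouse 2. Cdkn1a, Krt18 (1.68-fold) and the urokinase receptor gene Plaur (1.17-fold) rose in the planned test, 3 genes over all genes and 3 adjusted over the list alone. The fibrinogen chain genes Fga, Fgb and Fgg went the other way, with mean log2 differences of -0.58, -0.63 and -0.26. Without the tied pairs 12 injury genes passed as higher and 2 as lower.

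Extracellular matrix and fibroblast genes were higher in both mice at 21 of 24 tested genes, with medians of 1.22 in mouse 1 and 0.53 in mouse 2 (camera adjusted p = 0.0053; adjusted p = 0.872 with an estimated correlation). Timp1, a metalloproteinase inhibitor, was 11.9-fold and 1.77-fold higher, and the fibrillar collagens Col3a1, Col1a1 and Col1a2 were 7.05-fold, 6.98-fold and 4.43-fold higher in mouse 1 and 2.09-fold, 2.02-fold and 1.90-fold in mouse 2. No member passed the planned test by either adjustment, and 18 passed as higher without the tied pairs. Among 11 smooth muscle genes, Acta2 was 2.18-fold higher in mouse 1 and 1.16-fold in mouse 2, and Tagln 2.29-fold and 1.10-fold (list camera adjusted p = 0.50), and no member passed the planned test by either adjustment (2 as higher without the tied pairs). Urothelial genes were mixed: 7 of 15 were higher and 3 lower in both mice (camera adjusted p = 0.46). The keratins Krt15 (3.40-fold and 2.19-fold), Krt19 (2.70-fold and 1.54-fold) and Krt5 (2.00-fold and 1.54-fold) were higher, while the 5 uroplakins, proteins of the mature urothelial surface, had a median difference of 0 in mouse 1 and -0.07 in mouse 2. No urothelial gene passed the planned test by either adjustment (4 as higher without the tied pairs), and the list median, at percentile 100 of matched random lists, turned negative in the upper 40% of probe sets. Endothelial genes were higher in both mice at 13 of 14 genes with a median of 0.35 in mouse 1 and 0.39 in mouse 2 (camera adjusted p = 4.6e-05; adjusted p = 0.872 with an estimated correlation). The stem cell and endothelial antigen gene Cd34 (1.59-fold) and the fenestral diaphragm gene Plvap (1.27-fold) rose in the planned test, 2 genes over all genes and 4 adjusted over the list alone, and Vwf, von Willebrand factor, was 1.86-fold and 2.00-fold higher.

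The medians of the B and plasma cell (percentile 98.61), neutrophil (99.62) and smooth muscle (99.52) lists also lay above the middle 95% of matched random lists without a camera call, as did those of the podocyte (98.54) and ER stress and redox (99.28) lists described further on.

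**Figure D2:**
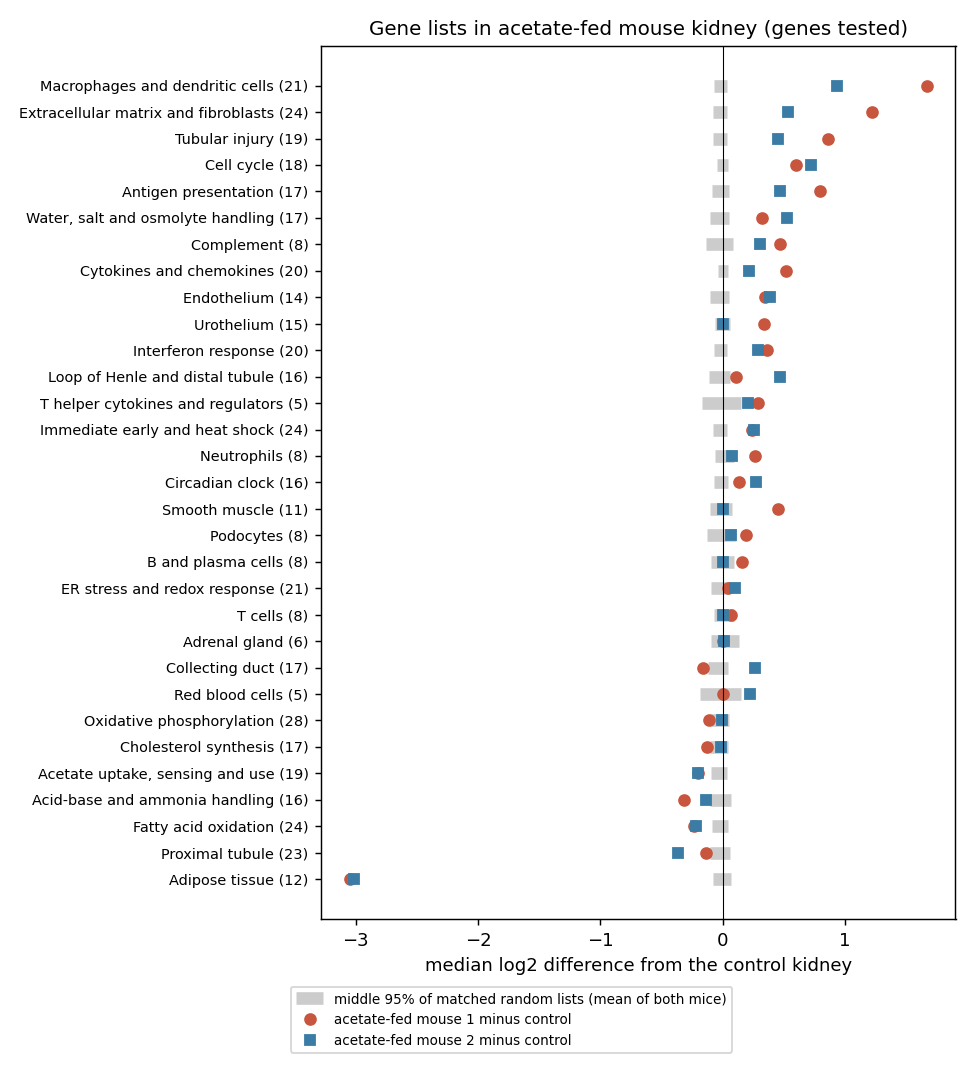
Median log2 difference from the control kidney (x axis) for each gene list with at least 5 tested genes (number of genes in brackets), in acetate-fed mouse 1 (circles) and acetate-fed mouse 2 (squares), with the middle 95% of medians of random lists matched on mean value (grey bars). Adipose genes sit near -3 in both mice, and the macrophage, matrix and injury medians are higher in mouse 1 than in mouse 2.

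Proximal tubule genes were lower in both mice at 16 of 23 tested genes and higher at 3, with medians of -0.14 in mouse 1 and -0.37 in mouse 2 (camera adjusted p = 0.044; adjusted p = 0.872 with an estimated correlation). Cyp2e1, a cytochrome that oxidises ethanol and small solvents, was 4.06-fold and 5.92-fold lower, the dicarboxylate transporter Slc13a3 2.15-fold and 2.87-fold lower, and Pck1, the gluconeogenic enzyme PEPCK, 2.40-fold and 2.05-fold lower. The 3 tested Slc13a3 probe sets ranged from -1.39 to -0.09 on the log2 scale. Among the 3 higher in both mice, Slc7a13, an amino acid transporter of the late proximal tubule, was 4.27-fold and 7.74-fold higher. No member passed the planned test by either adjustment, while without the tied pairs 8 passed as lower and 1 as higher, and the camera call of the list was lost with no filter (adjusted p = 0.063). Loop of Henle and distal tubule genes did not pass as a list (camera adjusted p = 0.19), although 11 of 16 were higher in both mice and their median of 0.25 lay at percentile 100 of matched random lists. Slc12a1, the target of loop diuretics, was 1.41-fold and 1.64-fold higher. The claudins Cldn14 and Cldn19 were 1.57-fold and 1.38-fold higher in mouse 1 and 1.67-fold and 1.69-fold in mouse 2, and Umod, uromodulin, was 13.53 in the control and 13.65 ± 0.03 in the acetate-fed kidneys. Collecting duct genes had medians of opposite sign, -0.16 in mouse 1 and 0.27 in mouse 2 (camera adjusted p = 0.67). The water channel genes Aqp2 and Aqp4 were 1.42-fold and 1.50-fold higher in mouse 1 and 2.18-fold and 1.87-fold in mouse 2, and the ammonia channel gene Rhbg was 2.19-fold and 1.38-fold lower. Of 8 podocyte genes 5 were higher and 1 lower in both mice (camera adjusted p = 0.21, and 0.032 with quantile normalization), with Ptpro 1.41-fold and 1.20-fold higher. No member of these last 3 lists passed the planned test by either adjustment. Without the tied pairs 4 loop and distal tubule genes passed as higher and 1 as lower, 3 collecting duct genes as higher and 1 as lower, and 0 podocyte genes.

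Genes of water, salt and osmolyte handling were higher in both mice at 13 of 17 tested genes (camera adjusted p = 0.0026; adjusted p = 0.872 with an estimated correlation). The glucocorticoid-induced Tsc22d3 was 2.10-fold and 2.04-fold higher, the betaine transporter Slc6a12 1.60-fold and 2.10-fold, the heat shock gene Hspa1b 1.37-fold and 2.16-fold, and the myo-inositol transporter Slc5a3 1.65-fold and 1.70-fold, with no member past the planned test by either adjustment and 9 past it as higher without the tied pairs. Acid-base and ammonia genes were lower in both mice at 11 of 16 and higher at 4, which did not pass as a list (camera adjusted p = 0.078; its median was -0.22, at percentile 0.03 of matched random lists, and its mean -0.09). The anion exchanger Slc26a6 (1.63-fold), the carbonic anhydrase Car4 (1.43-fold) and the glutamine transporter Slc38a3 (1.32-fold) fell in the planned test, 3 genes over all genes and 3 adjusted over the list alone. Without the tied pairs members passed in both directions, and Slc38a3 lost its call. Slc26a7 was 1.62-fold and 2.84-fold higher.

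Adipose genes were lower in both acetate-fed kidneys at all 12 tested genes, 9 of them at least 2-fold, with medians of -3.05 in mouse 1 and -3.02 in mouse 2 (camera adjusted p = 2.6e-05; adjusted p = 0.872 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, was 9.98 in the control and 4.12 ± 0.36 in the acetate-fed kidneys, 48.5-fold and 69.2-fold lower. Ucp1, the brown fat uncoupling protein, was 16.4-fold and 14.3-fold lower, Cidec 8.98-fold and 10.3-fold, and Retn, resistin, 8.35-fold and 10.1-fold. Adig was the 1 call over all genes, with 7 adjusted over the list alone. Fat cells also express many genes of the lipid lists that follow.

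Fatty acid oxidation genes were lower in both mice at 19 of 24 tested genes and higher at none (0 genes), with medians of -0.23 in mouse 1 and -0.22 in mouse 2 (camera adjusted p = 0.0083; adjusted p = 0.872 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase induced by PPAR alpha, was 3.10-fold and 5.67-fold lower, the peroxisomal Ehhadh 1.69-fold and 2.31-fold, and Fabp1 1.84-fold and 1.53-fold. Pdk4, which restrains pyruvate oxidation, fell 1.88-fold, the 1 call over all genes, with 0 adjusted over the list alone. Genes of acetate uptake, sensing and use were lower in both mice at 12 of 19 and higher at 4 (camera adjusted p = 0.047; adjusted p = 0.872 with an estimated correlation). Fasn, fatty acid synthase, was 1.93-fold and 2.17-fold lower, the monocarboxylate transporter Slc16a1 1.50-fold and 1.96-fold, and the acetyl-CoA hydrolase Acot12 1.54-fold and 1.73-fold, while the desaturase Scd2 was 1.52-fold and 1.85-fold higher. Of the enzymes that activate acetate, the mitochondrial Acss1 was 11.11 in the control and 11.16 ± 0.06 in the acetate-fed kidneys, and the cytosolic Acss2 10.32 and 10.17 ± 0.07. The acetate receptor gene Ffar2 was listed at 4.76 on all 3 arrays, and Hcar2 fell 1.18-fold, the 1 call by either adjustment. Cholesterol synthesis genes did not pass as a list (camera adjusted p = 0.39), with Mvd 1.55-fold and 1.46-fold lower and Dhcr7 the 1 call, 1.11-fold higher, by either adjustment. The acetate-fed values of Dhcr7 were exactly tied, and the members that passed without the tied pairs were all lower. Oxidative phosphorylation genes did not pass either (camera adjusted p = 0.39; median -0.11 in mouse 1), and 0 of 28 passed the planned test by either adjustment.

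Cell-cycle genes were higher in both mice at 16 of 18 tested genes, with medians of 0.60 in mouse 1 and 0.72 in mouse 2 (camera adjusted p = 0.0015; adjusted p = 0.872 with an estimated correlation). The mitotic kinase gene Cdk1 was 3.24-fold and 4.31-fold higher, cyclin gene Ccnb2 2.39-fold and 4.08-fold, the proliferation marker Mki67 2.58-fold and 2.92-fold, and the survivin gene Birc5 1.92-fold and 2.20-fold. Foxm1, a transcription factor of the mitotic genes, fell 1.15-fold, the 1 call over all genes, with 1 rise and 1 fall adjusted over the list alone. Its acetate-fed values were exactly tied, and the members that passed without the tied pairs were all higher. Immediate early and heat shock genes were higher in both mice at 15 of 24 and lower at 3 (camera adjusted p = 0.0026; adjusted p = 0.872 with an estimated correlation). Junb (1.69-fold), Klf2 (1.15-fold) and Jund (1.13-fold) rose in the planned test, 3 genes over all genes and 3 adjusted over the list alone, and the cytokine feedback gene Socs3 was 4.05-fold and 1.66-fold higher. Clock genes did not pass as a list (camera adjusted p = 0.23; median 0.15, at percentile 99.96 of matched random lists), with Per1 1.44-fold and 1.94-fold higher and Ciart 1.23-fold and 1.98-fold. Of the 16 tested clock genes, 7 were higher and 1 lower in both mice. The ER stress and redox list did not pass (camera adjusted p = 0.39), with Gclc, the rate-limiting enzyme of glutathione synthesis, 2.37-fold and 1.93-fold lower and the metallothionein gene Mt2 1.90-fold and 1.69-fold higher. No clock, ER stress or redox gene passed the planned test by either adjustment. Without the tied pairs 2 clock genes passed as higher, and 3 ER stress and redox genes as higher and 2 as lower.

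**Figure D3:**
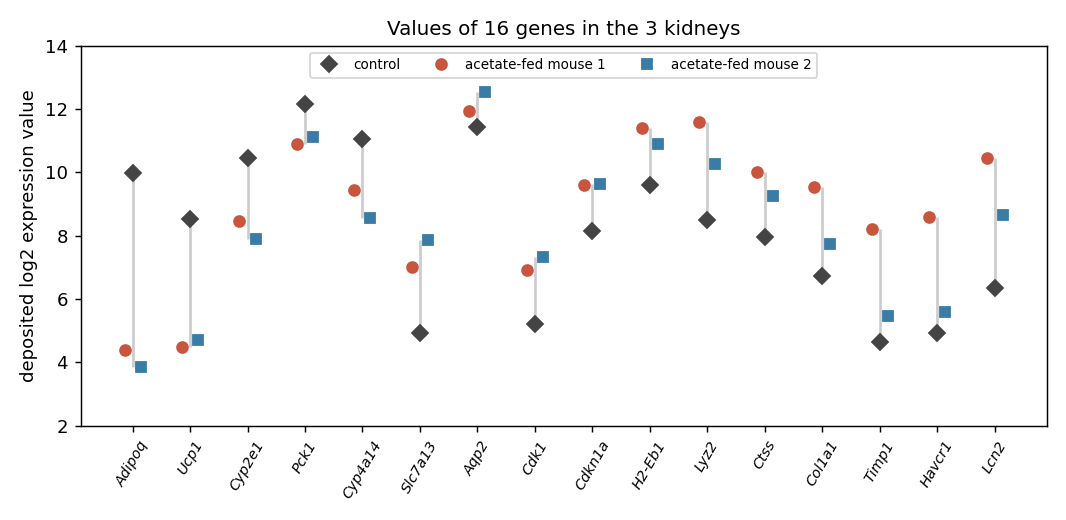
Deposited log2 expression value (y axis) of 16 genes in the control kidney (diamonds), acetate-fed mouse 1 (circles) and acetate-fed mouse 2 (squares); grey lines span the 3 values of a gene. Lcn2, Havcr1, Timp1 and Col1a1 lie further from the control in mouse 1 than in mouse 2, while Adipoq and Ucp1 are low in both acetate-fed kidneys.

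The lists for tissues that could have been carried over, other than fat, did not pass. Of 6 adrenal genes, Mrap, which is also made by fat cells, was 2.94-fold and 3.09-fold lower, and the steroid 21-hydroxylase Cyp21a1 was 5.95 in the control and 5.96 ± 0.02 in the acetate-fed kidneys, a difference whose sign turned, as did that of the list median, under quantile normalization and median centring (list camera adjusted p = 0.75; 0 members past the planned test, 1 adjusted over the list alone). Of 5 red blood cell genes, Alas2, the erythroid heme synthesis enzyme, was 2.58-fold lower in mouse 1 and 1.43-fold higher in mouse 2 (list camera adjusted p = 0.67; 0 members past the planned test by either adjustment). The female-specific Xist was 11.80 in the control and 11.94 ± 0.13 in the acetate-fed kidneys, and the Y-linked Eif2s3y stayed between 2.42 and 2.66 on all 3 arrays. The Gapdh control probe sets differed from the control array by -0.02 to 0.00 on average at the start, middle and end of the transcript. The actin control probe set at the end of the transcript was 13.30 in the control, 13.52 in mouse 1 and 13.29 in mouse 2, and that at its start 12.80, 13.10 and 12.82. Other control probe sets differed with the group: those for the Dap, Thr, Phe and Lys poly-A spikes, added to the RNA before labelling, were all lower on both acetate-fed arrays, with mean differences between -1.02 and -0.06. The 18S ribosomal RNA control differed by -0.25 at its start and 0.23 at its end, and the pyruvate carboxylase control by -0.30 at its start and -0.76 at its end.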

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

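The tie-free fit and the tests of ties were chosen after the results were seen. The planned count of 1400 higher and 1446 lower probe sets went to 3140 and 3383 with no filter, to 0 and 0 in the upper 40% of probe sets, with quantile normalization and with median centring, where 3513, 4333 and 4783 had an unadjusted p under 0.05. It went to 1174 and 890 when exactly tied acetate-fed pairs were left out. Quantile normalization and median centring break the ties by construction, and 92.3% of the planned calls were exact ties. Simulated unchanged arrays with the observed share of ties gave 9195 calls on average and without ties 0.3, so the planned calls are consistent with resting on the ties, although that simulation overshoots the 2846 observed. Of the 2846 planned calls, 2627 were tied pairs that the tie-free fit leaves out by construction, and 106 probe sets were called in both fits. All 190 probe sets at least 2-fold apart in both mice passed without the tied pairs. The small prior SD of that fit (0.12) largely sets this outcome, so neither figure measures robustness. With each library in turn set against the other pair, the planned test called 2846 probe sets for the control and 0 for acetate-fed mouse 1 or 2, where the remaining pair was tied at 29.1% and 28.0% of probe sets against 33.7%. Of the tested probe sets, 20.5% were tied on all 3 arrays and cannot be called in any split. These shares therefore overstate the ties that could be called, most in proportion where the share is smallest. In the simulation tied pairs still differed from the control, so more of its ties could be called. Why the other splits gave no calls was not tested. The 3 such splits are too few for a share under 0.05. The 190 probe sets at least 2-fold apart in both mice became 80 with a pseudocount of 64, which shrinks low values, and ranged from 306 to 508 when a single acetate-fed mouse was used, since agreement of both was no longer asked; the other settings stayed within 1.5 times. Camera called 15 lists, and between 14 and 20 under the other settings with a preset correlation, 13 to 15 of them shared with the 15. Lost were Proximal tubule and T helper cytokines and regulators with no filter and Cytokines and chemokines in the upper 40%, while the T helper list had too few genes for a test in the upper 40% and without tied pairs; the Neutrophils, Complement, Loop of Henle and distal tubule, Urothelium, Acid-base and Circadian clock lists were called without tied pairs. Also gained were T cells with no filter, Acid-base in the upper 40%, Podocytes with quantile normalization, and Loop of Henle and distal tubule and Circadian clock with quantile normalization and with median centring. With an estimated correlation it called 0, as the simulations did for a truly shifted list. Leaving out a mouse allowed no test. Directions were compared for the tested lists and 189 named genes, and only where both values were at least 0.005 in size. This leaves out the Collecting duct list (median 0.0045). Directions turned for the Urothelium list in the upper 40% of probe sets (median -0.0076), the Adrenal gland list (-0.030 with quantile normalization and -0.015 with median centring) and Cyp21a1 (-0.023 and -0.0092 under the same settings). With each acetate-fed mouse left out in turn they also turned for Alas2 (-1.37 to 0.52), Bpgm (-0.12 to 0.038) and Jchain (-0.26 to 0.98), where leaving out mouse 1 turned the sign. The cause was not tested. The naming rule put genes with the same direction in both mice first, so few of the 189 could turn when a mouse was left out. List members outside the 189 also differed in direction, such as Dbp (-1.10 in mouse 1, 0.81 in mouse 2) and Igha (0.87 and -0.45). Over the alternatives for 189 genes, 131 entries lost the call, 118 gained it and 5 turned direction. The other 1768 kept direction and, where a test was run, side of the threshold. They include the settings with a mouse left out, which had no test, and values under 0.005, whose direction was not compared. No paired analysis was possible because the 3 arrays come from separate mice and the labels name no pairs.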

Other observations

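The tests of further adipose genes and further glucocorticoid targets were set down before those genes were looked at; the other tests in this part were chosen after the results were seen, and so were the genes of this paragraph, a pick from those with large changes in both mice that lie outside the fixed lists. Among genes higher in both mice, D17H6S56E-5 was 5.24-fold and 5.59-fold higher, Zbtb16, a transcriptional repressor, 3.78-fold and 4.17-fold, the secreted glycoprotein gene Stc1 4.36-fold and 3.33-fold, the matrix protein tenascin C gene Tnc 7.63-fold and 3.14-fold, and the glucocorticoid-induced chaperone gene Fkbp5 2.72-fold and 2.84-fold. The kinase gene Plk3 was 2.70-fold and 3.31-fold higher. Among genes lower in both, the organic anion transporter genes Slc22a26 and Slc22a22 were 3.62-fold and 3.90-fold lower in mouse 1 and 8.93-fold and 4.35-fold in mouse 2. The carboxylesterase gene Ces2b was 3.50-fold and 6.73-fold lower, and Bhmt, which remethylates homocysteine with betaine, 3.58-fold and 5.69-fold. Haptoglobin, Hp, was 4.45-fold and 6.14-fold lower, Rnf24 4.59-fold and 5.20-fold, and the apolipoprotein gene Apoc1 4.10-fold and 4.74-fold.

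Adipose transcripts were lower in both acetate-fed kidneys. A candidate explanation is fat left on the control kidney. Of 18 further adipose genes, none of them in the fixed lists, 12 were tested, 6 were lower and 0 higher in both mice, and their median of -0.167 lay at percentile 0.15 of matched random lists, although 4 of the 12 were above the median of tested genes in the acetate-fed kidneys too; Slc36a2 was 2.28-fold lower and Tshr was listed at the same value on all arrays. A percentile this low is weak support, since the acid-base list lay at 0.03 without a camera call. Less fat around the kidney in acetate-fed mice predicts the same adipose values, and with 1 control library it cannot be told apart from fat on that sample. Lower Fasn, Pck1, Car3 and Thrsp (4.80-fold and 4.10-fold) are open to both, since fat cells express them strongly.

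Macrophage, matrix and injury transcripts were higher in both acetate-fed kidneys and most in mouse 1. A lower share of tubule cells alone would shift other cell types alike, and the medians in these 3 kidneys did not shift alike. The macrophage median exceeded the endothelial median by 0.922 (95% bootstrap interval over genes 0.597 to 1.19). Macrophage medians were 1.67 in mouse 1 and 0.93 in mouse 2, and endothelial medians 0.35 and 0.39. Genes are not replicates, so the interval holds no spread between mice or of the control. Both lists were picked after their medians were seen, so the interval describes this gap and tests nothing. Differentiated urothelium carried over in mouse 1 is argued against by the 5 uroplakins, whose median difference there was 0, between -0.27 and 0.09. Among the 64 tested genes of the 3 lists, mouse 1 stood at least 2-fold from both others at 16, the control at 12 and mouse 2 at 0, so these genes do not single out the control. A state particular to mouse 1 alone would leave mouse 2 like the control. The mouse 2 medians of 0.93 (macrophage), 0.53 (matrix) and 0.45 (injury) argue against it as the whole account, and it could cover only the excess in mouse 1. Acetate feeding and a single deviating control mouse cannot be told apart with 1 control measured. The poly-A spikes also differed between the control and the acetate-fed arrays, and a difference in RNA handling was not tested.

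Several genes known as glucocorticoid targets (Zbtb16, Fkbp5, Tsc22d3, Per1) were higher in both mice, and a glucocorticoid response may be a common source. Of 17 further targets, none of them in the fixed lists, 11 were higher and 3 lower in both mice, with a median of 0.303, above all 10000 matched random lists (percentile 100). The loop of Henle and distal tubule (100) and complement (99.99) lists also lay that high without a camera call, so such a percentile is weak support. Ddit4 was 2.75-fold, Bcl6 2.23-fold and Usp2 2.21-fold higher on average, while Irs2 was 1.80-fold lower. Pck1 and Pdk4 of the fixed lists, known as targets too, also went the other way. The mean log2 differences were -1.68 and -1.15 on the 2 tested Pck1 probe sets and -0.91 for Pdk4. Usp2 and Per1 also follow the daily clock, and Cebpb and Nfkbia also respond to inflammation, so the time of sacrifice and inflammation stay open. Dbp, of the clock list, was 2.14-fold lower in mouse 1 and 1.75-fold higher in mouse 2. The glucocorticoid hypothesis was found and tested in the same 3 kidneys.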
